A study of Homo sapiens with 4 samples.

How the data were processed

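The 4 arrays of this series are hybridisations of Clone2 RNA (4 Gy, 6 h) against RNA of unirradiated Clone10, 2 in each dye orientation. Per the labels, slides were scanned with ScanArray Express and quantified with QuantArray 3.0. Per the labels, the spreadsheet macro Normaliser2 then transformed the data and removed spots of poor quality. Its limits were a signal under 2.5 times the subarray background, a spot intensity under 5%, and streaks or damage. The deposited values are log2 ratios per spot, per the labels background-subtracted and normalised by regression within each subarray. All 19200 spots of every array nevertheless held a value, and the spot flags were not used here. Exact zeros numbered 479 on R1 and 4, 2 and 1 on R2, R3 and R4. The scale is stated, while the numerator of the ratio and the centring are not given in the sources used here. Signal intensities were not analysed here, so the signal over background behind a ratio is unknown, and the number of arrays limits the precision.

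Spot identifiers hold 4 numbers, read as the row (12) and column (4) of the subarray and the row (20) and column (20) of the spot, which makes 48 subarrays of 400 spots. This reading rests on the values, since horizontally adjacent spots correlated across spots with r from 0.32 to 0.64 on the deposited values of the 4 arrays. Gene names came from the platform annotation supplied for these spots. It gave 1 symbol to 10914 spots and several to 1435, and listed no gene for 6851. Gene identifiers of 10882 spots with 1 symbol were found in a current gene table, which updated 0 symbols. The match of spots to genes could not be tested against scanner output. Spots with 1 and the same symbol were averaged into a feature, and every other spot was a feature of its own, which gave 15784 features, 7498 of them with a gene symbol and 2345 of more than 1 spot. No genome build was given, so coordinates are not printed.

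The sign rule used the mean of the 4 Pearson correlations, across features, between arrays of opposite dye orientation. Its value was -0.0756, below 0, so R1 and R2 were sign-turned. The correlations themselves were small, -0.105 for R1 with R3, -0.0893 for R1 with R4, -0.0790 for R2 with R3 and -0.0296 for R2 with R4. Arrays of the same orientation correlated with r of 0.0619 (R1 with R2) and 0.348 (R3 with R4). Features are not independent replicates, and no p is attached to these values.

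The fit used limma 3.58.1 in R 4.3.3 with coefficients for the sample contrast and for a dye effect per feature, moderated by eBayes, with Benjamini-Hochberg adjustment and a two-sided threshold of 0.05. There were 2 residual and 1.62 prior degrees of freedom. Intervals are moderated 95% intervals from this fit, and SDs are over the 4 turned arrays, with dye differences left in. The labels leave open whether the 4 arrays share the same pooled extracts. If they do, they are repeats of 1 pair of RNA samples, and the test compares those samples only. The 26 gene lists (genes induced by DNA damage, mitosis and G2/M, DNA replication, histones, double-strand break repair and checkpoint, excision and mismatch repair, apoptosis regulators, antioxidant and NRF2, metallothioneins, interferon response, NF-kB targets, immediate early genes, heat shock and chaperones, unfolded protein response, ribosomal proteins, oxidative phosphorylation, proteasome, translation factors, glycolysis and hypoxia, cholesterol synthesis, colon epithelium, WNT targets, fibroblast and matrix, leukocytes, erythroid with liver and endothelium, growth factor receptors and signalling) were tested with camera at a preset correlation of 0.01. List medians over the arrays are given relative to the median of all features. Those of single arrays are turned ratios without that subtraction. Plots were drawn with matplotlib 3.10.9.

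The tests, the lists, the rule for named genes and the settings tried beside the main ones were fixed before the data were examined, apart from those named at the end. The rule took, where fewer than 10 features of a sign passed, the 10 of that sign with the largest mean among those of a single sign on all arrays, then for each list up to 2 members with the smallest p, and CDKN1A, MDM2 and GADD45A where measured. A further gene of the rule is not reported here. The rule excluded symbols of no known gene. The pattern that put this into practice (LOC, KIAA, LINC, FAM and TMEM names and open reading frames) was written after the data had been seen, and FAM and TMEM names can belong to known genes. The rule named 74 genes.

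The fit was tested on simulated data, with each array's 15784 values shuffled over features and 200 features changed by known amounts in each of 10 runs. Mean fitted changes were 1.00, 1.99, 2.98 and 3.96 for simulated log2 changes of 1, 2, 3 and 4. At an unadjusted p under 0.05 the fit found 50.0%, 87.8%, 96.8% and 99.2% of these features and 2.33% of unchanged ones. After adjustment it found 0% at every size, whereas on simulated arrays with an even SD of 0.30 it found 100% at every size. Camera found a simulated list of 40 features shifted by a log2 of 1 in 20 of 20 runs. Alternatives covered the dye term, missing values, centring, scaling, single spots, the prior, the turning of the arrays, each array left out, thresholds and list tests. Centring or detrending within subarrays, array weights, removal of outer subarrays, removal of exact zeros and 11 combinations of such settings were added after the data had been seen.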

Results

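The series compared RNA of an irradiated, X-ray resistant clone of HCT116 cells with RNA of an unirradiated clone of the same line on 4 spotted cDNA microarrays. HCT116 is an established human colorectal carcinoma line. The resistant clone, Clone2, received 4 Gy of X-rays and was harvested after 6 h. The control, Clone10, responds to radiation much as the parental line does, per the labels. Every array carried both RNAs in different dyes, so each value is a log2 ratio between the clones. On R1 and R2 Clone2 was labelled with Cy3 and Clone10 with Cy5, and on R3 and R4 the dyes were reversed. Clone and irradiation changed together in this design, so a ratio measured both at once. The labels describe RNA pooled from several batches, and p-values then measure the spread between these arrays, which may be technical.

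Each array gave 19200 values. Which clone stood in the numerator is not given in the sources used here. Ratios of R1 and R2 were therefore sign-turned by a rule on the correlations between arrays, and turned ratios are called positive or negative without a clone attached. A positive turned ratio means more RNA in Clone2 if the deposited ratio was Cy5 over Cy3, and less if it was Cy3 over Cy5. If the same clone was the numerator on every array, no array should have been turned, and a turned mean is then a dye difference that says nothing about the clones. The arrays differed in spread. The SD of the deposited log2 ratios was 1.72 on R1, 0.90 on R2, 0.50 on R3 and 0.79 on R4. The medians were 0.57, -0.07, 0.03 and 0.01. Ratios beyond 2-fold made up 50.1% of the spots on R1, 20.9% on R2, 5.51% on R3 and 9.74% on R4. The median of the first column of subarrays on R1 was 2.57, and that of the first row of subarrays on R4 was -1.18.

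**Figure D1:**
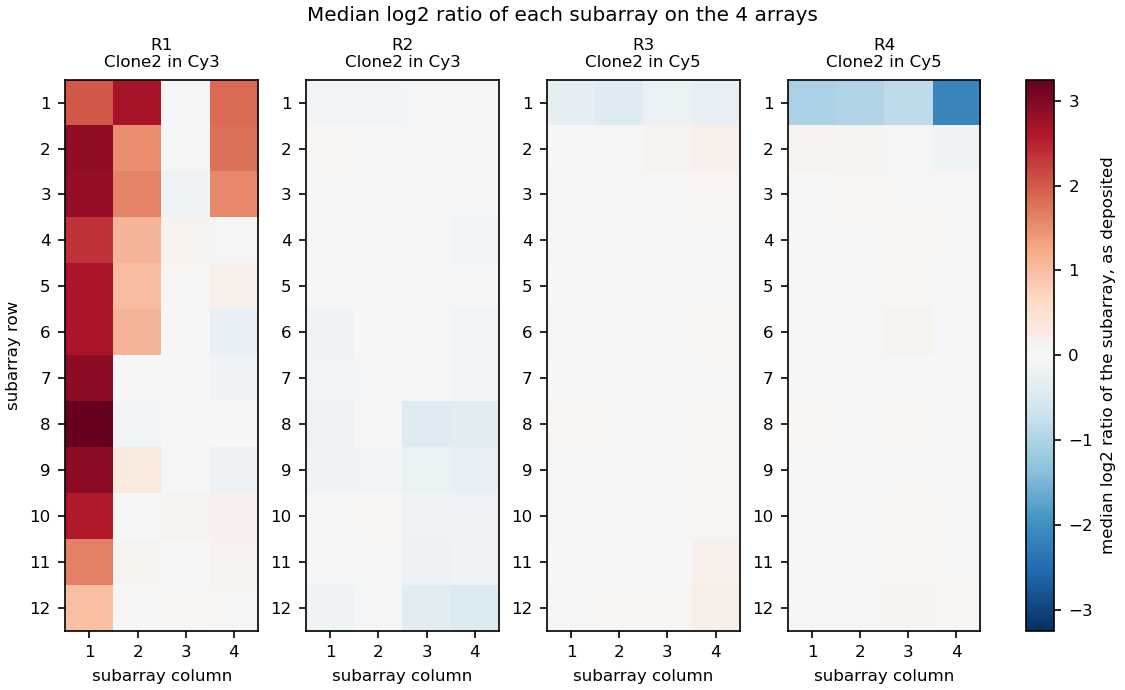
Median deposited log2 ratio of each of the 48 subarrays on the 4 arrays, by row and column of the subarray on the slide, with red above 0 and blue below 0. The first column of R1 stands above 0, with a highest subarray median of 3.25, and the first row of R4 stands below 0, with a lowest of -2.16.

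The comparison asked which genes differed between irradiated Clone2 and unirradiated Clone10. No gene passed the threshold, and the largest ratios differed widely between arrays. EGFR, the epidermal growth factor receptor, had the most negative mean among the named genes, -3.07 ± 2.45 (SD, n = 4 arrays), with a moderated 95% interval from -6.28 to 0.13. TAF6, a subunit of the general transcription factor TFIID, had a mean of -2.75 ± 2.26. PAOX, a polyamine oxidase, had -2.40 ± 1.64, and ENTPD6, a nucleotide-hydrolysing enzyme, had -2.39 ± 1.68. PLIN1, a coat protein of lipid droplets, had -2.35 ± 1.64. KCNA6, a voltage-gated potassium channel, had -2.30 ± 2.07, with an interval from -3.39 to -1.21 beside a dye term of 1.68. The means of TUBGCP6, NRN1, LTV1 and USP46 lay between -2.21 and -2.15. Of these 10 negative genes, 8 had a spot in the first row of subarrays, which holds 8.33% of all spots. With each subarray centred on its median the mean of EGFR was -2.08 and that of TAF6 -1.92, while PAOX had -1.57, ENTPD6 -1.39, PLIN1 -1.28, TUBGCP6 -1.15, USP46 -1.12 and LTV1 -1.09. With the median of neighbouring spots subtracted instead, EGFR had -1.66, TAF6 -0.98, PAOX -0.60, ENTPD6 -1.58, PLIN1 -0.37, TUBGCP6 -0.78, USP46 -0.29 and LTV1 -0.68. The naming rule applied to centred values picked 5 of the 20 genes that it named from deposited values. Without R1 the mean was -2.02 for EGFR, -1.48 for TAF6, -1.40 for PAOX, -1.38 for ENTPD6 and -1.44 for LTV1. Without R4 it was -1.11 for TUBGCP6 and -1.26 for LTV1, and without R3 it was -3.32 for TUBGCP6. The order of these genes also rests on the turning, whose rule had a mean correlation of only -0.0756. With all 4 arrays turned the mean was 0.41 for EGFR, -0.27 for TAF6, -0.011 for PAOX, -0.26 for ENTPD6, 0.35 for PLIN1, 1.61 for TUBGCP6, 0.58 for USP46, -0.41 for NRN1, -0.033 for LTV1 and -1.68 for KCNA6.

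On the positive side the highest mean was that of RNF217, a RING-finger ubiquitin ligase, at 2.41 ± 3.90 (SD, n = 4 arrays). Its ratio was 8.22 on R1 and between 0.13 and 1.07 on the others. HNRNPF, an RNA-binding splicing regulator, averaged 1.62 ± 2.32, and NDUFAF1, an assembly factor of respiratory complex I, 1.58 ± 2.45. SIGLEC15, a sialic acid binding lectin, averaged 1.58 ± 2.80 and had 5.79 on R2. The kinase PAK5 averaged 1.55 ± 1.22 and the splicing factor SUGP1 1.52 ± 1.02. PIP4P2, a phosphoinositide phosphatase, averaged 1.50 ± 1.29, with an interval from 0.93 to 2.07 beside a dye term of -1.10. Its mean was 0.95 with the median of neighbouring spots subtracted and 0.52 with array weights, centred subarrays and no dye term. The mitochondrial deacylase SIRT5 and the torsin ATPase TOR3A both averaged 1.49, and GLIPR1 averaged 1.48. Single arrays set several of these means. Without R1 the mean was 0.62 for RNF217, 0.58 for HNRNPF, 0.32 for NDUFAF1, 1.01 for SUGP1, 0.97 for SIRT5 and 2.96 for SIGLEC15, and without R2 it was 0.20 for SIGLEC15, 4.20 for RNF217, 2.67 for HNRNPF and 2.85 for NDUFAF1. With all 4 arrays turned the means of these 10 genes were positive, at 2.23 for RNF217, 0.76 for PAK5 and 0.43 for SUGP1. Such a mean is positive wherever the turned ratios of R1 and R2 sum to more than those of R3 and R4. With no array turned the same means are negative by construction, so their sign says nothing about stability. The reading with all arrays turned was chosen after both had been seen. None of the 10 genes had a spot in the first row of subarrays.

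**Figure D2:**
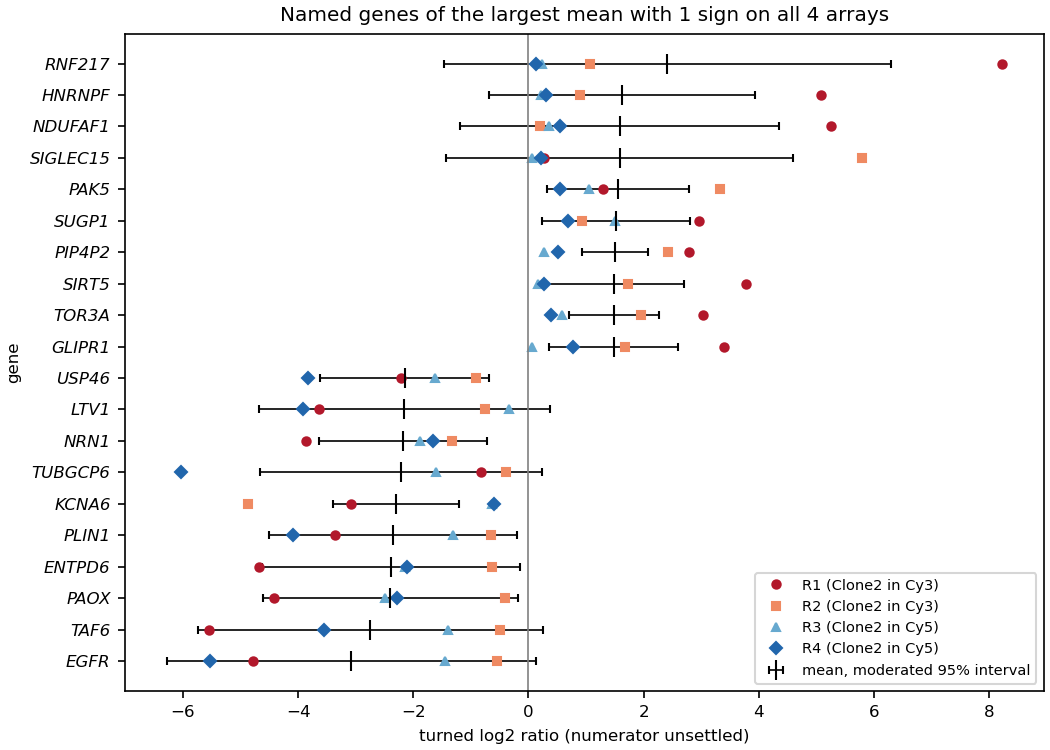
Turned log2 ratios of the 20 genes with the largest positive and negative means among those of a single sign on all 4 arrays, with 1 coloured point per array, a black tick for the mean and a bar for its moderated 95% interval. For RNF217 the point of R1 stands at 8.22 with the other arrays at or below 1.07, and for EGFR the points run from -5.53 on R4 to -0.54 on R2.

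Of 15784 features tested with limma, 0 had a Benjamini-Hochberg adjusted p under 0.05 and the lowest adjusted p was 0.637. At an unadjusted p under 0.05 there were 1118 features, or 7.08%, of which 373 were positive and 745 negative. The dye term of the same fit had 0 features past the adjusted threshold and 731 at an unadjusted p under 0.05. A contrast of R1 and R3 against R2 and R4, which neither dye nor clone follows, had 0 and 112 in a fit without the sample term. That fit counts differences shared by the turned arrays as error, while the main fit counts this contrast as error. The 112 is therefore not a like background for 1118 or 731. The turned ratio had a single sign on all 4 arrays for 3469 features, 22.0%. With no array turned 2145 features, 13.6%, had a single sign. The mean of both shares, 17.8%, is what agreement within each dye orientation alone would give if both signs were equally common there. The turned median of R1 was -0.61, so the signs were not balanced and 17.8% is only a rough guide. The turning rule used the same values, so the larger share was expected on the turned side. Of these features 1427 were positive and 2042 negative. At least 2-fold on every array were 0 positive and 11 negative features. A sign pattern that neither dye nor clone follows, R1 against the other arrays as deposited, gave 21. Of the 11, the only feature with a gene symbol was NRN1, a neuronal membrane protein, with -3.86, -1.34, -1.88 and -1.66 on R1 to R4. The median over all features was -0.20, and -0.0074 with each subarray centred. Without R2 the fit called 6746 features, and without R1 it called 0 with a lowest adjusted p of 0.104. In both cases the residual comes wholly from R3 against R4, so these fits differ only in the values of the lone array, R1 or R2. The larger count thus comes from the values of R1, whose deposited SD was 1.72 against 0.90 on R2, set against that error. In simulated arrays with the spread of the real ones, 0% of features changed 16-fold were called after adjustment. The shuffling removed the agreement within a dye orientation, such as the r of 0.348 of R3 with R4. The power in the real arrays may therefore differ, and the absence of calls was not shown to bound the differences between the clones.

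The fixed gene lists held 602 measured genes, and 31 of them had an unadjusted p under 0.05. None passed the threshold adjusted over all features, and 1 passed when adjusted over the list alone. That gene was CASP10, an initiator caspase of the death receptor pathway, among the 21 measured apoptosis regulators. Its turned ratio was -2.69, -2.67, -0.43 and -0.46 on R1 to R4, with a mean of -1.56 and an interval from -2.08 to -1.05. The interval leaves out the gap between the dye orientations, which the fit gave to a dye term of 1.11. With all 4 arrays turned the mean was -1.11. Its adjusted p by limma was 0.0306 over the list alone and 0.637 over all features. The first was not adjusted for the number of lists. No list member passed over its list alone without the dye term, with each array centred on its median or with all 4 arrays turned. DAPK3, a kinase that promotes cell death, had a mean of 0.63 ± 0.63. The remaining apoptosis regulators had an unadjusted p above 0.05, and the list as a group lay 0.03 below the median of all features (camera adjusted p 0.916).

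Genes induced by DNA damage did not pass the test as a group. Their median over 21 measured members lay 0.08 above that of all features. CDKN1A, an inhibitor of cyclin-dependent kinases, had a mean of 0.22 with an interval from -0.41 to 0.85, and single values of 0.21, 0.86, -0.02 and -0.18. Its mean was 0.78 with each subarray centred, 0.38 without R1 and 0.054 without R2. GADD45A, a stress sensor induced by DNA damage, had a mean of -0.22 with an interval from -1.16 to 0.72. Its mean was 0.14 without R1, -0.58 without R2 and -0.071 with subarrays centred. HBEGF and EPHA2 had the lowest p of the list, with means of 0.60 ± 0.65 and 0.60 ± 0.63, and EPHA2 had 0.32 without R1. MDM2 was not analysed here. Of the DNA damage-induced genes 2 were positive on all 4 arrays, 1 was negative on all, and 18 had mixed signs.

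Cell cycle and DNA repair lists did not pass the test either. The 28 mitosis and G2/M genes had a median 0.06 below all features, with 1 positive and 4 negative on all arrays. In that list the cyclin CCNB2 had -1.15 ± 0.93 as deposited and -0.085 with subarrays centred or -0.59 without R1, and the anaphase-promoting complex subunit CDC27 had 0.47 ± 0.51, or 0.31 without R2. The 31 DNA replication genes had a median 0.20 above all features. Their lowest p values belonged to the polymerase subunit POLD3, with 0.49 ± 0.31, and the replication licensing factor CDC6, with -0.59 ± 1.03 as deposited and 0.022 with subarrays centred. The 10 histone genes lay 0.26 below, with H4C11 at -0.55 ± 0.42 and H1-2 at -0.49 ± 0.30, and the centred mean of H4C11 was -0.19. The 19 genes of double-strand break repair and checkpoints lay 0.07 below. Among them XRCC5, the large subunit of the Ku complex that binds broken DNA ends, had -0.59 ± 0.36 and RAD1 -0.71 ± 1.08, or -0.41 without R1. The 22 genes of excision and mismatch repair lay 0.25 above all features, although ERCC1 and ERCC2, which act in nucleotide excision repair, had means of -0.61 ± 0.37 and -0.61 ± 0.40. The centred mean of ERCC1 was -0.34. The camera adjusted p was 0.838 for the DNA damage-induced, mitosis, replication and histone lists and 0.876 for both repair lists.

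Ribosomal proteins had the lowest p of all lists by camera with the preset correlation, and did not pass after adjustment. Of 43 measured genes 14 were negative on all 4 arrays and 2 positive, and 6 had an unadjusted p under 0.05, all negative. Their median over the arrays lay 0.07 below all features. In turned ratios it was -0.51 on R1, above the -0.61 of all features there. On R2 to R4 it was -0.19, -0.16 and -0.092, against 0.075, 0.022 and 0.0090 for all features. With subarrays centred the list had 0.33, -0.31, -0.21 and -0.087 on R1 to R4 and a median of 0.0050 over the arrays. RPS18 had a mean of -1.14 ± 0.71 and RPL35A -1.46 ± 1.20. RPL35A lies in the first row of subarrays and had -0.40 with subarrays centred. The camera p of 0.0471 became 0.838 after adjustment. With an estimated correlation the unadjusted p was 0.251, and with subarrays centred the unadjusted p was 0.633. The 29 translation factors lay 0.06 above all features (camera adjusted p 0.876), and EIF5A had -1.59 ± 1.25 and EIF4A2 -0.54 ± 0.56. Without R1 EIF5A had -0.83, and without R4 EIF4A2 had -0.35. The 26 proteasome genes lay 0.08 below (camera adjusted p 0.916), with PSMB4 at -0.92 ± 0.88 and PSMD5 at 0.98 ± 1.97. The 43 oxidative phosphorylation genes lay 0.08 below, with COX5B at 0.73 ± 0.59 and NDUFS1 at -0.66 ± 0.23. Subarray centring gave -0.37 for PSMB4 and -0.36 for NDUFS1.

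No stress or metabolic list passed the test. The 38 antioxidant and NRF2 genes had a median 0.06 above all features. The haem oxygenase HMOX2 had a mean of 1.25 ± 1.03 and the thioredoxin reductase TXNRD1 1.09 ± 0.91, both positive on all arrays. The 5 metallothioneins lay 0.24 below, with MT1G at -0.59 ± 0.56 over 5 spots and MT1H at -0.43 ± 0.33 as deposited but 0.18 with subarrays centred. The 27 interferon response genes lay 0.13 below, with 5 negative and 0 positive on all arrays, and IFIH1, a sensor of double-stranded RNA, had -0.76 ± 0.71 and IRF1 -0.93 ± 1.45. The 16 NF-kB targets lay 0.12 above, with CD83 at 0.68 ± 0.78 and NFKB2 at -0.79 ± 0.98. The 16 immediate early genes lay 0.19 above, with the phosphatase DUSP6 at -1.02 ± 0.73 and EGR3 at -1.40 ± 2.03. The 16 heat shock genes and chaperones lay 0.31 below, with HSPA1A at -0.78 ± 0.47 and CCT6A at -1.47 ± 1.67. The 15 genes of the unfolded protein response lay 0.02 below (camera adjusted p 0.876), with HERPUD1 at 0.80 ± 0.68 and the sensor kinase ERN1 at 0.74 ± 0.31. The 21 glycolysis and hypoxia genes lay 0.04 below, with PKM at -0.47 ± 0.40 and VEGFA at -1.50 ± 2.00. The 14 cholesterol synthesis genes lay 0.03 below (camera adjusted p 0.876), with TM7SF2 at -0.76 ± 0.86 and the desaturase SCD at -0.43 ± 0.38 as deposited and 0.28 with subarrays centred. Several of these means were smaller with subarrays centred, at -0.17 for MT1G, -0.29 for IRF1, -0.41 for EGR3, -0.29 for HSPA1A, -0.40 for CCT6A, -0.21 for PKM, -0.80 for VEGFA and -0.31 for TM7SF2, while HMOX2 had 2.08. Without R1 the mean was -0.29 for MT1G, -0.39 for IRF1, -0.42 for NFKB2, -0.38 for EGR3, -0.87 for CCT6A and -0.71 for VEGFA. Without R2 it was 0.70 for TXNRD1, 0.45 for CD83, -0.89 for MT1G, -1.47 for IRF1, -2.43 for EGR3 and -2.30 for VEGFA. For the lists of this paragraph without a stated value, and for oxidative phosphorylation, the camera adjusted p was 0.838.

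Markers of the colon epithelium, 20 measured, lay 0.18 above all features (camera adjusted p 0.947). The trefoil factors TFF3 and TFF1 had means of -1.01 ± 0.82 and -0.52 ± 0.52, and TFF3 had -0.66 without R1. The 18 WNT targets lay 0.07 below (camera adjusted p 0.907), with MMP7 at -0.40 ± 0.50 and ZNRF3 at 0.80 ± 1.02, or 0.30 without R2 and 1.30 without R1. The 37 growth factor receptors and signalling genes lay 0.17 below (camera adjusted p 0.838), with the ligand TGFB2 at 0.78 ± 0.60 and the receptor FGFR2 at -1.07 ± 0.72 as deposited, -0.56 with subarrays centred and -0.68 without R1. Markers of cells other than epithelium did not pass the test. The 34 fibroblast and matrix genes lay 0.03 below, with POSTN at -0.59 ± 0.89, or -0.20 with subarrays centred, and S100A4 at -0.61 ± 0.68. The 21 leukocyte genes lay 0.17 above, with CD3D at 1.06 ± 1.50 and FCER1G at 0.55 ± 0.35, and both lists had a camera adjusted p of 0.838. The 22 genes of erythroid cells, liver and endothelium lay 0.06 above (camera adjusted p 0.947), with CDH5 at 0.70 ± 0.61 and ENG at -0.74 ± 0.89, or -0.41 without R1.

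**Figure D3:**
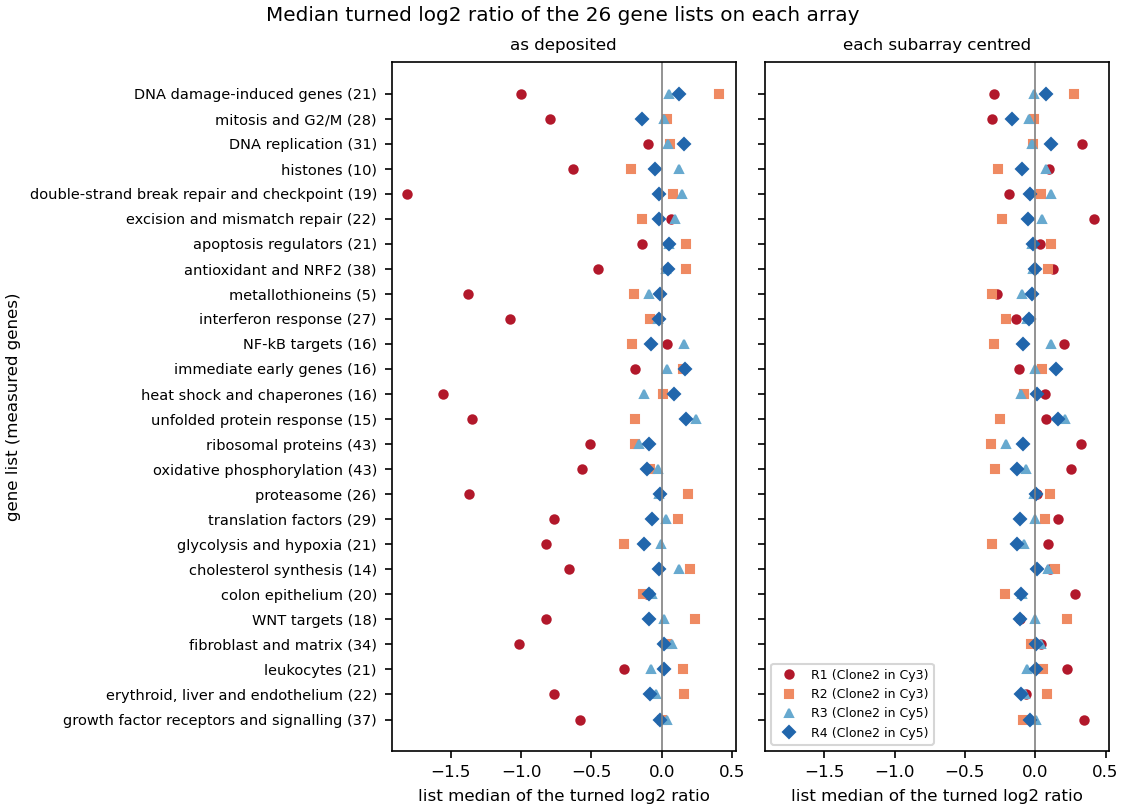
Median turned log2 ratio of each of the 26 gene lists on each array, as deposited on the left and with each subarray centred on the right, with 1 coloured point per array and the number of measured genes beside each list. Without centring, 24 turned list medians of R1 lie below 0, and with subarrays centred 8 do.

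None of the 26 lists passed the threshold. The lowest adjusted p was 0.838 by camera with the preset correlation, 0.977 with an estimated correlation, 0.620 by camera on ranks and 0.511 by fry. Without adjustment 1 list, the ribosomal proteins, had a p under 0.05 by camera with the preset correlation, 2 lists did on ranks (metallothioneins at 0.0415 and ribosomal proteins at 0.0477), and 0 did with an estimated correlation, where the lowest p was 0.241 for leukocytes. By fry 1 list had a p under 0.05, the histones at 0.0419. The median, the mean and the direction of the test did not share a sign for the histones, apoptosis regulators, unfolded protein response, proteasome, translation factors, cholesterol synthesis, WNT targets and the erythroid, liver and endothelium list.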

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

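All tests of explanations in this part were chosen after related values had been seen. A check for 1 array standing apart from the other 3 covered 108 items and marked 18. Chance marks about 1 in 20 for arrays of equal spread, but here the SD ran from 0.50 on R3 to 1.72 on R1. All 8 marked lists had R1 apart and share its offset. The number marked is therefore not a measure of excess over chance. The genes chosen for large means, 10 of each sign, are favoured for such marks by that choice. Most of the other genes were chosen for a small p within a list.

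In deposited ratios array R1 stood apart with 479 exact zeros, a median of 0.57 and a highest subarray median of 3.25. R4 stood apart with a lowest subarray median of -2.16. The values of lists and genes that follow are turned ratios, in which the offset of R1 has the opposite sign. On R1 the turned medians of 8 lists stood apart, at -1.81 for double-strand break repair and checkpoint, -1.38 for metallothioneins, -1.08 for the interferon response, -1.56 for heat shock and chaperones, -0.56 for oxidative phosphorylation, -1.37 for the proteasome, -1.02 for fibroblast and matrix genes and -0.58 for growth factor receptors and signalling. Among the genes, R1 stood apart for RNF217 (8.22), HNRNPF (5.07), NDUFAF1 (5.25) and EPHA2 (1.54), and R2 for SIGLEC15 (5.79) and ZNRF3 (2.32).

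The turned list medians of R1 were offset together, and 24 of 26 lay below 0, against 8 with each subarray centred. For spots of one gene in different subarrays, the difference in R1 ratio followed the difference of the subarray medians with a slope of 0.867 (95% bootstrap interval 0.815 to 0.913), where 1 would be a pure position offset. Position effects that the normalisation within subarrays did not remove would give such a slope. Different spots of a gene correlated at only 0.0266 within an array, however, so spots of unrelated genes could give it too. The slope alone therefore does not settle the cause. Genes that differ between the RNA pools and share subarrays would put like medians on the other arrays, and the highest correlation of turned subarray medians with R1 was 0.286 (bootstrap interval 0.141 to 0.503). The upper end of that interval reaches the bound of 0.5 set for the test, so the correlation, which ignores size, cannot decide. In size the arrays differed, since the first column of subarrays had a deposited median of 2.57 on R1 and -0.061, 0.018 and 0.017 on R2 to R4. If the arrays hold the same RNA, these medians argue against such genes as the source of the offset in that column.

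The largest negative ratios lay together in the first row of subarrays, with 8 of the 10 negative named genes there, EGFR and TAF6 among them. With each subarray centred, the naming rule put 2 genes of that row among its 10 negative ones, within the 3 that a binomial limit allows, but centring lowers that number by construction. The rule then put 8 genes of the row among its 10 positive ones, above the same limit. Centred ratios in that row had an SD of 1.98 on R4 and 0.98 on R3, against 0.47 and 0.42 in the other rows, while R1 had 1.56 against 1.38 and R2 0.64 against 0.91. As deposited the row had 8 of the negative and 0 of the positive genes, so its excess on the negative side went with its offset. The row stayed prominent once the offset was removed. How much the offset left by the normalisation and the wider spread on R3 and R4 each added cannot be told apart. A difference between the clones in the genes of this row was not tested separately.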

How the results depend on the processing

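The counts of features, dye-specific features, lists and list members past the adjusted threshold were 0 under every alternative run with all 4 arrays, planned or added after the data had been seen, and the lowest adjusted p for features ranged from 0.0996 to 0.795 among them. The exception was the count of features of one sign and at least 2-fold on every array, 11, which uses no test. Requiring 3 values changed nothing, since none is missing. Leaving out each array in turn gave 0 to 6746 features, 0 to 5865 dye-specific features, 0 to 248 list members and 0 to 252 members over the list alone. The high ends come without R2, and without R1 0 features and 15 members over the list alone passed. With 3 arrays the lone array of an orientation is fitted exactly and is assumed to vary like the others, so 1 pair of arrays sets the error. The pair, and so the error, is the same without R1 as without R2, and the difference between them comes from the values of the lone array. That array is R1 without R2, and R2 without R1, with SDs of the deposited ratios of 1.72 and 0.90. Whether the spread or the offset of R1 gave the calls was not tested. Features at an unadjusted p under 0.05 then ranged from 48 to 8666 and for the dye term from 20 to 7957.

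Without the dye term 693 features had an unadjusted p under 0.05, with scaling of the arrays 1920, and with array weights, centred subarrays and no dye term 2824. Among combinations, for which only features were counted, array weights gave 625 and, without the dye term, 2867. Subarray centring and scaling with weights gave 2187, and 2421 without the dye term. Subtracting the median of neighbouring spots with weights and no dye term gave 2502. For the dye term scaling gave 1379. Turning R3 and R4 as well as R1 and R2 exchanges the sample and dye terms of the fit, so its counts of 731 and, for the dye term, 1118 follow by construction and say nothing about stability. It left 2145 features of one sign. Members past the threshold over the list alone numbered 0 without the dye term, 0 with each array centred, 0 with all arrays turned, 3 with scaling, 2 with single spots and 9 with weights, centred subarrays and no dye term. The causes of these shifts were not tested.

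Means of 74 named genes moved by over 1.5 times for 28 with subarrays centred, 27 without R1, 14 without R2, 1 without R3 and 3 without R4. Such moves were not counted for the other settings, some of which moved means as far. Weights with centred subarrays and no dye term gave 0.41 for RNF217, 0.42 for SIGLEC15 and 0.36 for SIRT5, against 2.41, 1.58 and 1.49 as deposited. Subtracting neighbours gave 0.25 for HBEGF, against 0.60, but 2.23 for RNF217. Of these 74 genes 3 had the other sign with subarrays centred (CDC6 0.022, MT1H 0.18, SCD 0.28) and 4 with neighbours subtracted (H4C11 0.15, MT1H 0.13, MT1G 0.16, SCD 0.40). With weights, centred subarrays and no dye term 7 did (CDC6 0.18, IRF1 0.017, EGR3 0.19, PSMB4 0.18, PSMD5 -0.40, POSTN 0.052, CDKN1A -0.0022). The highest single spot differed in sign for MT1G (0.25), HSPA1A (0.083) and GADD45A (0.060), as did HSPA1A without the outer subarrays (0.083). Leaving out each array in turn gave -0.58 to 0.14 for GADD45A, the high end without R1, and turned no other named gene. With R3 and R4 turned as well as R1 and R2, the mean becomes the dye term with its sign turned, and 10 did, EGFR 0.41, PLIN1 0.35, TUBGCP6 1.61, USP46 0.58, HMOX2 -0.82, CCT6A 1.11, ERN1 -0.14, RPL35A 0.91, NDUFS1 0.021 and EIF5A 0.13. That reading fixes no overall sign. Its mirror with no array turned, which was computed first, reversed 64, and the reading with 10 was chosen after both had been seen. The causes were not tested.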

Other observations

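Tests of explanations in this part were chosen after related values had been seen, and the genes named here were chosen after their values were seen. Genes with 2 spots in different subarrays give a check between spots of a gene, on means and signs over the 4 turned arrays. Of 1547 such genes, with subarrays centred, 52.7% had spot means of the same sign. Both spots had a single sign on all 4 arrays for 68 genes, and the spots shared that sign for 42 and opposed each other for 26. Genes on the same arrays are not independent, and no p is attached to these shares. Among those sharing it, the spot means were -1.36 and -2.06 for PILRA, an inhibitory receptor of myeloid cells, and 0.90 and 1.04 for ELAVL1, which stabilises messenger RNAs. The colon trefoil factor TFF3 had -0.69 and -0.67, and the transcription factor MYC had 0.54 and 0.40.

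Turned ratios of opposite-dye arrays correlated at 0.0712 on average across spots, with a sign set by the turning rule itself. One sign on all 4 arrays was held by 3469 features and by up to 2627 under the other 7 sign patterns, and with 8 patterns, 1 of which reached that count, the share cannot fall below 0.05. Of 399 circular shifts of the spot grid of R1 and R2 within subarrays, 0 gave a mean correlation as large in either direction. The largest was 0.0388. Such shifts also move a position effect shared by the slides out of register, so they cannot decide whether one took part. A difference between the RNA pools that holds for a gene in all its spots is argued against as the whole cause, if the annotation of spots holds. Different spots of a gene correlated 0.0848 times as much between opposite-dye arrays as a spot with itself (bootstrap interval -0.0884 to 0.255, 2258 genes). Position effects shared by the slides, a mixture of causes and a factor tied to the single spot stay open. Such a factor may be the clone's own sequence, a spot printed or annotated as another gene, or a weak signal. If the same clone was the numerator on every array, it may also be a dye effect of the spot. None of these factors of the spot was tested.

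Adjacent spots resembled each other more than spots of one gene did. With subarrays centred, adjacent spots of different genes correlated across spots at 0.44, 0.28, 0.35 and 0.35 on R1 to R4, and different spots of one gene in other subarrays at 0.0266 within an array (bootstrap interval 0.0106 to 0.0419).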
